A study of Mus musculus with 6 samples.

How the data were processed

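RNA was measured in epithelial cells isolated from the submandibular gland of adult mice aged 12 weeks, in 3 p63 knockout and 3 wild-type samples. Per the labels' protocols, RNA was extracted with a Direct-zol kit, and libraries were made from total RNA with the Illumina TruSeq RNA kit. The deposited values are TPM, which the authors made from raw counts by correcting for library size and gene length, per the labels. Per the submitters' processing notes, the tools used were TopHat2 2.1.1, Bowtie2 2.2.6, featureCounts 1.5.1 and DESeq2 1.20.0, with the mm9 mouse genome. The gene annotation, gene lengths, strand setting, treatment of reads that match several genes and read counts were not given in the sources used here. The table is named as normalized counts, but each column summed to 1000000, as TPM does. TPM keeps no record of depth, so no counting error or detection limit was given. TPM values of 1 library are shares of a fixed total, so a few abundant genes can move all others. No coordinates were printed, because the values rest on mm9 and the reference used here was another build (GRCm38, GENCODE M21), which served only for gene names, GC content and transcript length.

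Groups were taken from the genotype label, and replicates were numbered within each group because the labels give no shared numbers. The first number and the library index number in the titles lie close together across the groups, in the same pairs. The labels state no pairing, so the main test used none. The labels name separate samples but do not say how the glands or mice were allotted to them, so p-values measure the spread between these samples. No date or batch was given. The comparison was knockout against wild type. Values were transformed to log2(TPM + 1), and fold changes on this scale understate the change of low genes. Of 23366 genes, the 11268 with at least 1 TPM in at least 3 libraries were tested with limma 3.58.1 (linear model, empirical Bayes moderation with a mean-variance trend) in R 4.3.3. Every adjusted p of a gene is limma's two-sided p with Benjamini-Hochberg adjustment over these genes, and 0.05 was the threshold. Means and SDs are of TPM, and SE is that of the log2 fold change.

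Before the data were examined, 31 lists of marker and pathway genes were written, together with the sample groups, the tests, the rule for named genes and all alternatives except those named as added later. The 29 lists with at least 3 measured members were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation as an alternative, and with fry for changes on balance in 1 direction and in either direction, each adjusted over the lists. A further set of sex chromosome genes checked the sex of the libraries. Named genes were Trp63 and Fst, the 8 largest rises and the 8 largest falls among genes that passed with no overlap between groups and had a settled name, and up to 3 passing genes of each list with the largest change. By this rule 21 genes were named. Other genes are examples that were chosen after their values were seen. A few genes of the lists are counted in them but not reported here by name.

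The alternatives tried were pseudocounts of 0.1 and 0.5 TPM, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, rescaling without the 50 most abundant genes, limma without trend, with robust moderation or with array weights, a block for libraries with neighbouring index numbers, a minimum log2 fold change of 1, and leaving out each library in turn. Alternatives chosen after seeing the data were the removal of each library's trend against GC content and transcript length, and leaving out knockout library 1 and wild-type libraries 1 and 2. GC content and length were found for 11089 of the genes tested (98.4%). Count-based tests were not run because the values are TPM, and a sex covariate was not needed because all libraries had the same sex pattern.

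The procedure was tested on simulated data for knockout against wild type, over 11048 genes with their real means. The spread of each gene was averaged over knockout and wild type and drawn independently for each gene and library. A library that departs over many genes at once, as knockout library 3 did, was not simulated. The shares called therefore hold only for libraries without such a departure. The procedure called 18.4% of genes changed 2-fold, 82.0% of those changed 4-fold, 94.0% of those changed 8-fold and 92.0% of those changed 16-fold, and 12 of 10849 unchanged genes. With no change simulated it called 0 genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.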

Results

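Gene expression was measured by RNA-seq in epithelial cells of the submandibular gland, one of the major salivary glands, from adult mice aged 12 weeks. There were 3 libraries from p63 knockout mice and 3 from wild-type mice. p63, encoded by Trp63, is a transcription factor of basal epithelial cells. The study asked what p63 does for the growth capacity of progenitor cells in this gland, and how follistatin (Fst), a secreted protein that binds and blocks activin, takes part in it. Each library held values for 23366 gene symbols in TPM, a transcript abundance scaled to a fixed total of 1000000 per library. Sequencing depth was therefore unknown. Between 10634 and 11235 genes reached 1 TPM in a library, and the 50 most abundant genes took 68.8% to 80.0% of the TPM. Knockout library 3 stood at an end of both ranges, with 10634 genes and 80.0%. The other libraries had 11129 to 11235 genes at 1 TPM and a share of 68.8% to 75.8%. Knockout library 3 also had the most genes at 0 TPM, 8254 against 6812 to 7797 in the others. Every library held transcripts of Y-linked genes, the lowest at 1.66 TPM, while Xist stayed at or below 0.0999 TPM. All 6 thus had the pattern of males.

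Trp63 was low in both groups and lower in the knockout. It stood at 1.59, 0.816 and 1.76 TPM in knockout libraries 1, 2 and 3 (n = 3). In wild-type libraries 1, 2 and 3 it stood at 3.48, 1.85 and 3.68 TPM (n = 3). The values of the groups did not overlap, with a log2 fold change of -0.74 (SE 0.27), but the gene did not pass the test over all genes (adjusted p = 0.27). Fst measured 4.32, 1.64 and 1.48 TPM in the knockout libraries and 5.90, 4.73 and 4.74 TPM in the wild-type libraries. Its log2 fold change was -0.90 (SE 0.32, adjusted p = 0.26), and it did not pass either. An exact two-sided permutation test gave p = 0.1 for each gene, the smallest value that 3 libraries against 3 allow. The labels do not say which exons the knockout removes, so the Trp63 reads that were left could not be assigned to intact or deleted parts of the gene. Without knockout library 3, Trp63 passed at -0.85 (adjusted p = 0.040), but so did 5127 of all 11268 genes tested. It passed in 2 of 19 alternatives (lowest adjusted p 0.024).

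Of all genes tested, 8 passed limma's test as higher in the knockout. The gene with the largest rise was Mup5, a major urinary protein that carries small lipophilic molecules, at 17751 ± 13759 TPM in the knockout and 505 ± 84.8 TPM in wild type (SD, n = 3 each, log2 fold change 4.87, SE 0.49, adjusted p = 0.015). Serpina3n, a secreted serine protease inhibitor, rose to 19.2 ± 13.5 TPM from 1.02 ± 0.0896 TPM (log2 fold change 3.12, SE 0.44, adjusted p = 0.044). The sugar phosphate exchanger gene Slc37a2 rose by 2.94 (SE 0.26, adjusted p = 0.014) and the folate hydrolase gene Folh1 by 2.94 (SE 0.28, adjusted p = 0.014). Cxcl13, a chemokine that attracts B cells, rose by 2.41 (SE 0.26, adjusted p = 0.019). Uhrf1, which keeps DNA methylation through replication, rose to 15.5 ± 2.46 TPM from 2.14 ± 0.423 TPM (log2 fold change 2.39, SE 0.23, adjusted p = 0.014). Chaf1b, a histone chaperone subunit that works at the replication fork, rose by 1.51 (SE 0.22, adjusted p = 0.045). The endocytosis gene Sh3bp4 rose by 1.89 (SE 0.20, adjusted p = 0.019). Of the 8 named genes with the largest falls, 3 were in none of the gene lists. Capn3, a calpain protease, fell to 1.21 ± 0.466 TPM from 15.7 ± 2.51 TPM (log2 fold change -2.93, SE 0.25, adjusted p = 0.014). Syt16, a member of the synaptotagmin family, fell too (log2 fold change -2.60, SE 0.22, adjusted p = 0.014). So did Gadd45a, a gene induced by DNA damage and growth arrest (9.65 ± 2.26 TPM against 62.4 ± 6.49 TPM, log2 fold change -2.59, SE 0.24, adjusted p = 0.014). The Chaf1b call was lost in 14 of 19 alternatives, among them median-of-ratios scaling, quantile normalization and the removal of GC and length trends (adjusted p over the alternatives 0.00074 to 1.0, log2 fold change 1.38 to 2.03). The calls were lost in 7 of 20 alternatives for Cxcl13, 6 of 20 each for Serpina3n, Uhrf1 and Sh3bp4, 5 of 20 for Mup5, 4 of 20 each for Slc37a2, Folh1, Capn3 and Gadd45a, and 2 of 19 for Syt16.

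In all, 44 of 11268 genes passed limma's test at an adjusted p of 0.05, with 8 higher and 36 lower in the knockout. The groups were fully apart for all 44 of these genes, and they did not overlap for 2373 of all genes tested (21.1%, where chance gives 10%). At an unadjusted p of 0.05 there were 1740 genes. The number and its balance depended on single libraries. Without knockout library 3 it was 5127, with most of them higher (3809 higher, 1318 lower), and array weights, which gave that library little weight, turned the balance in the same way (3477 higher, 1345 lower). It was 11 without knockout library 1 (3 higher, 8 lower) and 16 without knockout library 2 (3 higher, 13 lower). It was 1, 0 and 0 without wild-type libraries 1, 2 and 3 in turn, where 879, 1024 and 1020 genes had an unadjusted p under 0.05. Mup5 belongs to a family of near-identical copies, as do the Klk1b genes, so the share of reads given to each member is uncertain.

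**Figure D1:**
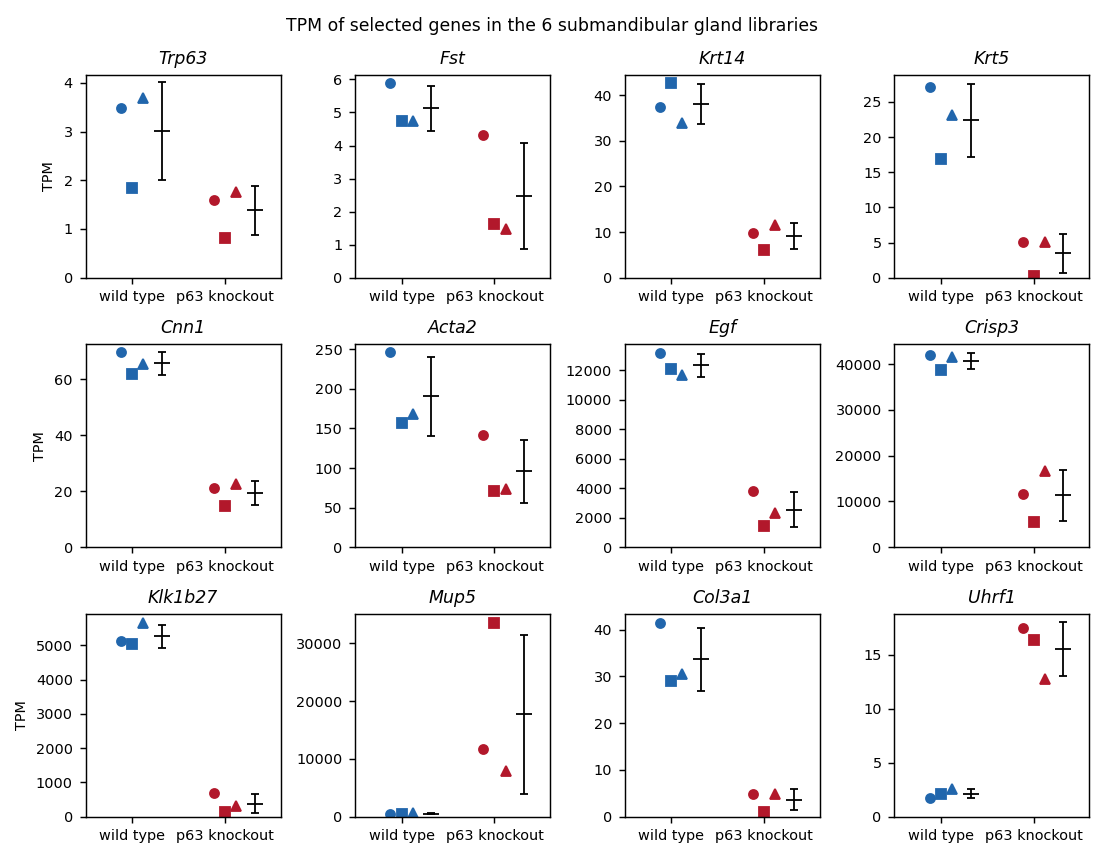
TPM of 12 genes in each of the 6 libraries, on linear axes that start at 0, with wild type in blue and p63 knockout in red. Circles, squares and triangles mark libraries 1, 2 and 3 of each group, and the black bars give the mean and SD. Krt14, Cnn1, Egf, Klk1b27, Col3a1, Mup5 and Uhrf1 passed the test, and Trp63, Fst, Krt5, Acta2 and Crisp3 did not.

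Egf and 3 kallikrein genes fell in the knockout, all of them products of the granular convoluted tubule. This is the duct segment of the rodent submandibular gland that stores growth factors and kallikreins. Egf, encoding epidermal growth factor, fell to 2549 ± 1208 TPM from 12336 ± 772 TPM (SD, n = 3 each, log2 fold change -2.38, SE 0.34, adjusted p = 0.044). The kallikrein gene Klk1b27 fell to 383 ± 281 TPM from 5267 ± 333 TPM (log2 fold change -4.06, SE 0.50, adjusted p = 0.033). Klk1b24 (log2 fold change -2.71, SE 0.37, adjusted p = 0.037) and Klk1b16 (log2 fold change -2.36, SE 0.34, adjusted p = 0.047) fell as well. These were the 4 of 20 listed genes that passed over all genes. Under quantile normalization Egf was at -1.16 (adjusted p = 0.094, over the alternatives 0.00068 to 0.23) and Klk1b16 at -1.03 (adjusted p = 0.14, over the alternatives 0.00068 to 0.25), and both calls were lost. Over all alternatives the call was lost in 9 of 20 for Egf, 12 of 20 for Klk1b16, and 4 of 20 each for Klk1b27 and Klk1b24. Adjusted over the list alone, 15 were lower and 1 was higher. Crisp3, a secreted cysteine-rich protein, was among the 15, at a log2 fold change of -1.99 (adjusted p over all genes = 0.069). The 1 in the other direction was Klk1, the tissue kallikrein, at 9805 ± 3188 TPM in the knockout and 5306 ± 968 TPM in wild type. The median log2 fold change of the list was -2.13 (camera adjusted p = 2.1e-11, but adjusted p = 0.43 with an estimated correlation), and it shrank to -1.18 under quantile normalization (camera adjusted p = 0.00068, over the alternatives 1.8e-63 to 0.43). By fry in 1 direction the list did not pass (adjusted p = 0.072). Set against the wild-type mean, the median of the list was -1.40, -2.98 and -1.97 in knockout libraries 1, 2 and 3.

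Krt14 and Cnn1, markers of the basal and myoepithelial cells that carry p63 in this gland, fell in the knockout. Smooth muscle shares contractile genes of the myoepithelial list, Cnn1 and Acta2 among them. Their fall therefore cannot be assigned to myoepithelial cells alone. Krt14, a keratin of basal cells, fell to 9.19 ± 2.83 TPM from 38.0 ± 4.39 TPM (SD, n = 3 each, log2 fold change -1.97, SE 0.27, adjusted p = 0.037). It was the only 1 of 16 basal genes that passed over all genes. Adjusted over the list alone, 6 were lower and 0 higher. Among them were the partner keratin Krt5 at 3.45 ± 2.82 TPM against 22.4 ± 5.15 TPM (adjusted p over all genes = 0.099) and the neurotrophin receptor gene Ngfr at 18.7 ± 18.2 TPM against 86.0 ± 11.5 TPM (adjusted p = 0.098). The hemidesmosome collagen gene Col17a1 was another, at a log2 fold change of -1.27 (adjusted p = 0.093). The median over the basal list was -0.63 (camera adjusted p = 3.0e-06, but adjusted p = 0.42 with an estimated correlation, and fry adjusted p = 0.042). Of 14 myoepithelial genes, the calponin gene Cnn1 passed, falling to 19.5 ± 4.30 TPM from 65.7 ± 4.01 TPM (log2 fold change -1.73, SE 0.22, adjusted p = 0.035). Adjusted over the list alone, 7 were lower and 0 higher. They included smooth muscle actin (Acta2) at 95.7 ± 40.1 TPM against 190.4 ± 49.3 TPM (adjusted p over all genes = 0.20) and Actg2 at a log2 fold change of -2.17 (adjusted p = 0.066). The myoepithelial median was -0.81 (camera adjusted p = 4.5e-08, but adjusted p = 0.42 with an estimated correlation, and fry adjusted p = 0.048). The Krt14 call was lost in 12 of 20 alternatives (adjusted p 0.00036 to 1.0) and the Cnn1 call in 11 of 20 (adjusted p 0.00036 to 1.0). These included median-of-ratios scaling, quantile normalization, the removal of GC and length trends, and the block for neighbouring index numbers (adjusted p = 0.061 and 0.054). They also included each fit without 1 library except knockout library 3. Their log2 fold changes stayed within -2.20 to -1.73 and -1.90 to -1.54.

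Markers of stem and progenitor cells shared Krt14 and Krt5 with the basal list, and Krt14 was the 1 of 13 that passed. Adjusted over the list alone 3 were lower, the third being Cd24a (-0.68, adjusted p over all genes = 0.13). Kit (-0.59, adjusted p = 0.38) and Sox9 (-0.15, adjusted p = 0.73) were not. Of the 13 genes, 10 had negative and 3 positive log2 fold changes. The positive ones were Sox10 (1.17, adjusted p = 0.23), Prom1 (0.61, adjusted p = 0.35) and Bmi1 (0.19, adjusted p = 0.67). The list had a median of -0.32 (camera adjusted p = 0.031, but adjusted p = 0.43 with an estimated correlation). Its call was lost in 10 of 18 alternatives (adjusted p over all of them 0.0061 to 0.43). Among these were the fits without knockout library 2 (median -0.27, adjusted p = 0.074) and without wild-type library 3 (median -0.29, adjusted p = 0.064), no filter (median -0.20), the 5 TPM filter (median -0.32) and fry. The call was lost at somewhat larger medians under median-of-ratios scaling (-0.40), quantile normalization (-0.37), rescaling without the 50 most abundant genes (-0.38) and the removal of GC and length trends (-0.37). Of 34 listed target genes of p63, Krt14 alone passed, and 5 were lower adjusted over the list alone, namely Krt5, Krt14, Col17a1, Sfn and Jag2. The p63 targets did not pass as a list by camera (adjusted p = 0.68), but passed by fry for changes in either direction (adjusted p = 0.029). Their median of 0.19 had the opposite sign to their mean of -0.01 and to the direction of the test. By library it was 0.45, 0.24 and -0.24 in knockout libraries 1, 2 and 3, and over the alternatives it ranged from -0.06 to 0.34. Only Trp63 and Trp53 of the p63 family were measured above the filter, so that list was not tested as a set. Trp53 had a log2 fold change of -0.29 (adjusted p = 0.55). Neither gene passed, adjusted over the list alone or over all genes.

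**Figure D2:**
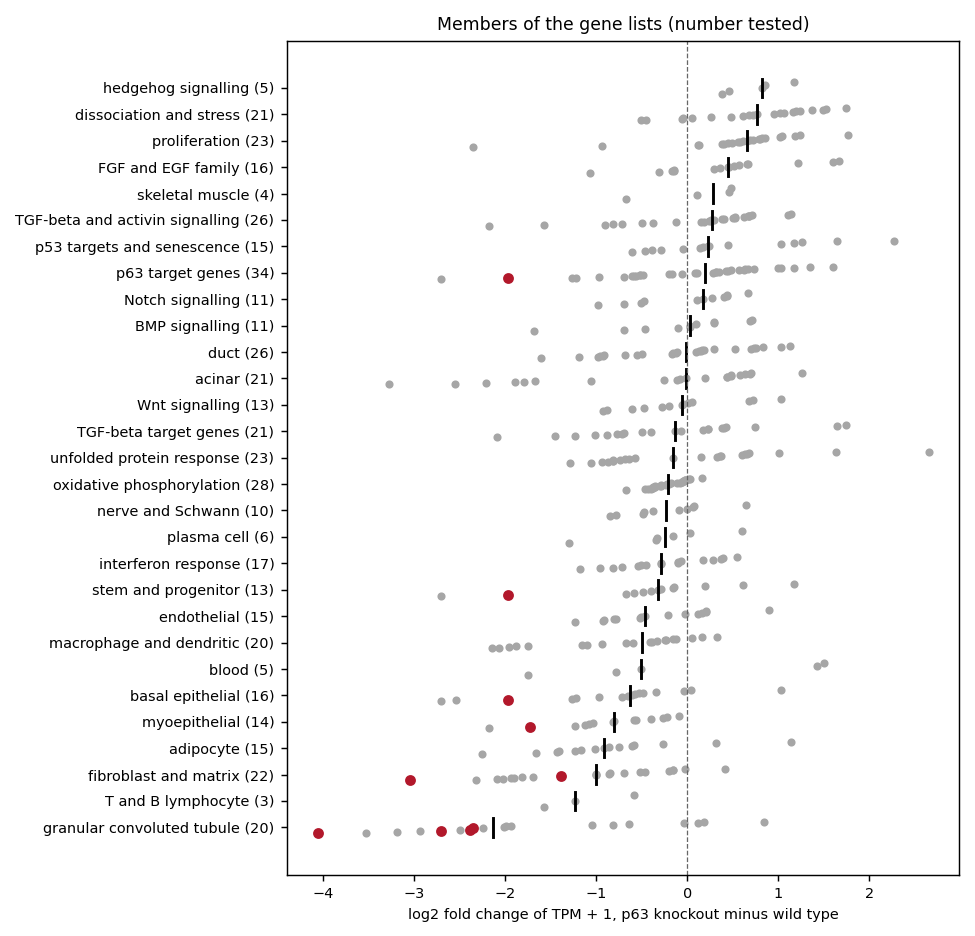
Log2 fold change of TPM + 1, p63 knockout minus wild type, for each member of the 29 lists tested, with the number of members in brackets. Red points passed the test over all genes, grey points did not, and black bars give the list medians, from -2.13 for the granular convoluted tubule to 0.83 for hedgehog signalling.

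Col3a1 and Col6a3, genes of the collagen matrix that fibroblasts make, fell in the knockout preparations, which were described as epithelial cells. The fibrillar collagen gene Col3a1 fell to 3.61 ± 2.22 TPM from 33.7 ± 6.73 TPM (SD, n = 3 each, log2 fold change -3.05, SE 0.43, adjusted p = 0.044). Col6a3 fell to 0.264 ± 0.190 TPM from 2.29 ± 0.174 TPM (log2 fold change -1.39, SE 0.18, adjusted p = 0.034). Their calls were lost in 9 of 20 alternatives for Col3a1 (adjusted p 0.00042 to 0.25) and 12 of 19 for Col6a3 (adjusted p 0.00061 to 0.40). With GC and length trends removed Col3a1 stood at -2.98 (adjusted p = 0.054) and Col6a3 at -1.69 (adjusted p = 0.074), against -3.05 and -1.39 before. They were the 2 of 22 that passed, and 11 were lower adjusted over the list alone. Among these were Col1a1 at -2.09 (adjusted p over all genes = 0.073) and Sparc at -1.81 (adjusted p = 0.092). The list had a median of -1.003 (camera adjusted p = 4.3e-10, but adjusted p = 0.49 with an estimated correlation, and fry adjusted p = 0.12). It stood at -0.55, -1.50 and -1.02 in knockout libraries 1, 2 and 3 against the wild-type mean. Of 20 macrophage and dendritic cell genes 0 passed over all genes in limma's test (9 at an unadjusted p under 0.05) and 9 were lower adjusted over the list alone. These included the class II antigen presentation gene H2-Aa at 35.6 ± 19.6 TPM against 147 ± 5.05 TPM (adjusted p = 0.059) and the lysozyme gene Lyz2 at 43.7 ± 5.07 TPM against 94.2 ± 6.13 TPM (adjusted p = 0.059). Their median was -0.50 (camera adjusted p = 2.2e-06, but adjusted p = 0.42 with an estimated correlation, and fry adjusted p = 0.063). Of 20 listed T and B lymphocyte genes, only 3, Cd52, Coro1a and Ptprc, were measured above the filter. Other white blood cells express these too, so they cannot single out lymphocytes. All 3 were lower adjusted over the list alone and 0 passed over all genes (3 at an unadjusted p under 0.05). Their median was -1.23 (camera adjusted p = 0.0011, but adjusted p = 0.42 with an estimated correlation, and fry adjusted p = 0.042).

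Among other cell types, 0 of 15 adipocyte genes passed over all genes (5 at an unadjusted p under 0.05) while 1, Pparg, was lower adjusted over the list alone (-0.86, adjusted p over all genes = 0.073). The adipocyte median was -0.92 (camera adjusted p = 0.00066, but adjusted p = 0.63 with an estimated correlation). Without the 3 libraries richest in markers of neighbouring glands, which leaves 2 knockout libraries against 1 wild-type library, it was -0.44 and the call was lost (adjusted p = 0.065, over the alternatives 2.0e-09 to 0.63), as it was by fry (adjusted p = 0.46). Adipocyte genes also differed within the wild-type group, with medians of 0.52, 0.41 and -0.79 in wild-type libraries 1, 2 and 3. Of 15 endothelial genes 0 passed either way (6 at an unadjusted p under 0.05). Their median was -0.46 (camera adjusted p = 0.031, but adjusted p = 0.43 with an estimated correlation). The call of that list was lost in 8 of 18 alternatives (adjusted p over all of them 0.019 to 0.43). Among these were the fit without knockout library 2 (median -0.39, adjusted p = 0.086), quantile normalization (median -0.27) and fry. The call was lost at larger medians with the 5 TPM filter (-0.65), median-of-ratios scaling (-0.49), rescaling without the 50 most abundant genes (-0.48) and the removal of GC and length trends (-0.65). Of 17 interferon response genes 0 passed (5 at an unadjusted p under 0.05) and 3, Bst2 and Gbp2 among them, were lower adjusted over the list alone. Their median was -0.29 (camera adjusted p = 0.022, but adjusted p = 0.63 with an estimated correlation). The interferon call was lost in 6 of 18 alternatives, among them the fits without knockout library 3 (median 0.02, adjusted p = 0.14) and without wild-type library 2 (median -0.18, adjusted p = 0.12), the 5 TPM filter and fry (adjusted p over all of them 0.00093 to 0.63). Of 5 blood cell genes 2 were higher (S100a8 and S100a9) and 2 lower (Pf4 among them) adjusted over the list alone, and 0 passed over all genes (4 at an unadjusted p under 0.05). The list did not pass by camera (adjusted p = 0.48), but passed by fry for changes in either direction (adjusted p = 0.016).

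The TGF-beta and activin list, of which follistatin acts on the activin part, showed few differences that stood above the spread. Of 26 measured genes 0 passed over all genes (5 at an unadjusted p under 0.05), and 2 were lower adjusted over the list alone. The first was the ligand gene Tgfb2, at 16.5 ± 9.21 TPM in the knockout and 72.1 ± 8.14 TPM in wild type (SD, n = 3 each, log2 fold change -2.18, SE 0.35, adjusted p = 0.057). The other was Fstl1, a secreted relative of follistatin, at 7.12 ± 1.69 TPM against 23.0 ± 3.58 TPM (log2 fold change -1.57, SE 0.24, adjusted p = 0.055). The activin subunit gene Inhbb had a log2 fold change of 0.26 (adjusted p = 0.74) and the inhibitory Smad7 0.40 (adjusted p = 0.42). The list had a median of 0.28 and did not pass (camera adjusted p = 0.73). That median differed in sign between libraries, at 0.71, 0.38 and -0.40 in knockout libraries 1, 2 and 3, and ranged from 0.04 to 0.55 over the alternatives, highest without knockout library 3. Of 21 target genes of TGF-beta, 0 passed over all genes (8 at an unadjusted p under 0.05) and 4 were lower adjusted over the list alone, namely Col1a1, Thbs1, Tagln and Snai2. This target list did not pass (median -0.13, camera adjusted p = 0.054), but did without knockout library 1 (median -0.32, adjusted p = 0.0075), without wild-type library 1 (median -0.09, adjusted p = 0.034) and without wild-type library 2 (median -0.23, adjusted p = 0.049). It also passed with the block for neighbouring index numbers and without the 3 libraries richest in markers of neighbouring glands (adjusted p over the alternatives 0.00035 to 0.63). Of 11 BMP signalling genes 0 passed either way (2 at an unadjusted p under 0.05, median 0.04, camera adjusted p = 0.78, with a mean of -0.07 of the opposite sign).

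Cell cycle genes were higher as a list, mainly in knockout library 3. The median of the list was 0.65 (camera adjusted p = 0.0023, but adjusted p = 0.64 with an estimated correlation). The call was also lost with the 5 TPM filter (adjusted p = 0.21) and by fry (adjusted p = 0.46, over the alternatives 2.4e-09 to 0.64). Of 23 proliferation genes 0 passed over all genes (9 at an unadjusted p under 0.05). Adjusted over the list alone 3 were higher, Ccne1, Mcm7 and Bub1b. In the same way 2 were lower, the G1 cyclin genes Ccnd1 (6.25 ± 6.64 TPM against 27.6 ± 5.75 TPM, adjusted p over all genes = 0.12) and Ccnd2. Mcm7, part of the replicative helicase, stood at 10.9 ± 0.879 TPM against 4.77 ± 0.528 TPM (SD, n = 3 each, adjusted p = 0.077). Against the wild-type mean the median of the list was 0.34, -0.05 and 1.42 in knockout libraries 1, 2 and 3. Without knockout library 3 the call was lost and the direction of the camera test turned (median 0.21, adjusted p = 0.43). Immediate early and stress genes, which respond to tissue dissociation, also rose as a list. Their median was 0.76 (camera adjusted p = 0.0011, but adjusted p = 0.63 with an estimated correlation, and fry adjusted p = 0.23). It was 1.54, 0.86 and 0.01 in knockout libraries 1, 2 and 3. Of 21, 0 passed over all genes (7 at an unadjusted p under 0.05), and 1, Fos, was higher adjusted over the list alone (3.09 ± 1.28 TPM against 0.412 ± 0.116 TPM, adjusted p over all genes = 0.064).

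Acinar cell genes, which encode secretory products of the other main cell type of the gland, did not pass as a list, which also held markers of neighbouring glands. Of 21, 0 passed either way (5 at an unadjusted p under 0.05), and the camera adjusted p was 0.55. The list median of -0.02 and mean of -0.43 were negative while the test pointed up. Of its genes, 7 mark the parotid or sublingual gland and varied widely within each group, with log2 fold changes of -3.28 to -0.02 (median -1.89). Of the 14 others, divided off after the values were seen, 10 had positive and 4 negative log2 fold changes, from -1.06 to 1.25 (median 0.46, not tested as a list). The 5 with an unadjusted p under 0.05 were all among these, with Spdef at 1.25 (adjusted p over all genes = 0.12), Car6 at 0.69 (adjusted p = 0.20), Pip at 0.70 (adjusted p = 0.29), Xbp1 at 0.63 (adjusted p = 0.31) and Agr2 at -1.06 (adjusted p = 0.16). The water channel gene Aqp5 measured 178 ± 26.1 TPM in the knockout and 187 ± 20.9 TPM in wild type (SD, n = 3 each). Of 26 duct genes 0 passed over all genes (8 at an unadjusted p under 0.05) and 3, Krt19, Krt7 and Gfra3, were lower adjusted over the list alone (median -0.01, camera adjusted p = 0.38). All 28 oxidative phosphorylation genes missed the threshold both ways (1 at an unadjusted p under 0.05). The list median was -0.21 (camera adjusted p = 0.0044, but adjusted p = 0.63 with an estimated correlation). Its call was also lost under quantile normalization (median -0.16, adjusted p = 0.092) and with GC and length trends removed (median -0.17, adjusted p = 0.054). It was lost too without the 3 libraries richest in markers of neighbouring glands (median -0.08, adjusted p = 0.52) and by fry (adjusted p = 0.12, over the alternatives 0.00059 to 0.63). Of 23 unfolded protein response genes 0 passed over all genes (11 at an unadjusted p under 0.05) and 5, Pdia4, Manf, Pdia6, Canx and Dnajc3, were lower adjusted over the list alone (median -0.16, camera adjusted p = 0.17). That list passed without the 3 libraries richest in markers of neighbouring glands (median -0.45, adjusted p = 0.020, over the alternatives 0.020 to 0.66). Of 13 Wnt signalling genes 0 passed over all genes (4 at an unadjusted p under 0.05) and 2, Sfrp1 and Nkd1, were lower adjusted over the list alone (median -0.06, camera adjusted p = 0.22, but fry adjusted p = 0.048 for changes in either direction).

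In 7 further lists no gene passed over all genes or adjusted over the list alone, and the lists did not pass by camera or by fry in one direction. Nerve and Schwann cell genes passed by fry for changes in either direction (adjusted p = 0.029). The number of genes at an unadjusted p under 0.05 lay between 0 and 3. The signalling and stress lists among them were Notch signalling (11 genes, median 0.18, camera adjusted p = 0.73, mean -0.01), the FGF and EGF family (16 genes, median 0.45, adjusted p = 0.22) and p53 targets and senescence (15 genes, median 0.23, adjusted p = 0.42). The cell type lists were plasma cells (6 genes, median -0.24, adjusted p = 0.41), skeletal muscle (4 genes, median 0.28, adjusted p = 0.68) and nerve and Schwann cells (10 genes, median -0.23, adjusted p = 0.12). Hedgehog signalling was the last (5 genes, median 0.83, adjusted p = 0.070). Hedgehog genes passed as a list without knockout library 3 (median 1.44, adjusted p = 0.024) and with the block for neighbouring index numbers (adjusted p = 0.046). Nerve and Schwann cell genes did so without knockout library 1 (median -0.31, adjusted p = 0.029) and without the 3 libraries richest in markers of neighbouring glands (median -0.40, adjusted p = 0.0091). Of the sublingual mucous genes 1 was measured above the filter and did not pass, adjusted over the list alone or over all genes (-0.27). Of the 29 lists tested, 11 were lower and 2 higher by camera with the preset correlation, and 0 held with an estimated correlation, where 2 had an unadjusted p under 0.05. By fry, 3 lists passed for a shift on balance in one direction (basal, myoepithelial, and T and B lymphocyte with 3 genes measured) and 13 for changes in either direction. The 13 were the lists of basal, myoepithelial, granular convoluted tubule, stem and progenitor, macrophage and dendritic, endothelial, fibroblast, nerve and Schwann and blood cell genes, p63 targets, Wnt signalling, interferon response and oxidative phosphorylation.

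The knockout libraries were not alike. The first principal component took 63.7% of the variance and placed knockout libraries 1 and 2 at 57.3 and 56.7. Knockout library 3 lay at -34.9, near wild-type libraries 1, 2 and 3 at -27.7, -25.8 and -25.7. The second component, with 17.6%, set knockout library 3 apart at -41.6. Across genes, the values of knockout library 3 correlated at 0.896 and 0.893 with knockout libraries 1 and 2. They correlated at 0.951, 0.956 and 0.963 with wild-type libraries 1, 2 and 3, where genes are not independent replicates.

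**Figure D3:**
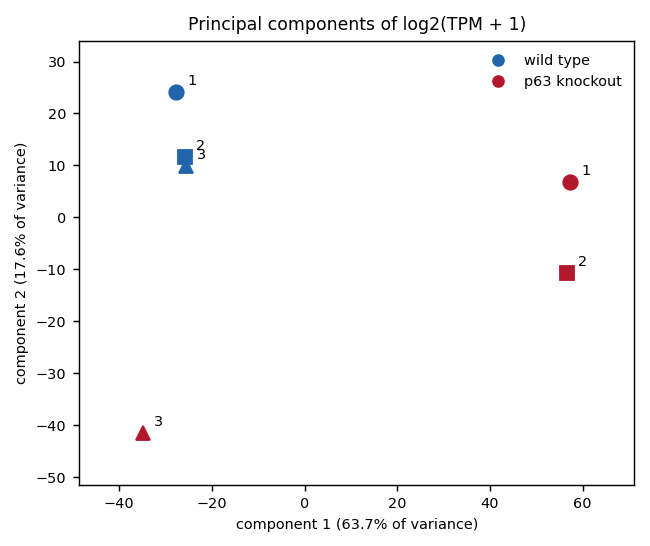
Scores of the 6 libraries on the principal components of log2(TPM + 1), with wild type in blue, p63 knockout in red and the library number beside each point. Knockout libraries 1 and 2 lie at 57.3 and 56.7 on the horizontal axis, which holds 63.7% of the variance, and knockout library 3 lies at -34.9.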

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

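Alternatives added after seeing the data are the removal of GC and length trends and the fit without knockout library 1 and wild-type libraries 1 and 2. All 44 called genes kept their sign under every alternative in which they were tested, but the number called moved. It was 25 (18 lower) with a pseudocount of 0.1, 11 (5 higher, 6 lower) with no filter, 29 (22 lower) with a filter of 5 TPM, 73 (15 higher, 58 lower) with median-of-ratios scaling, 72 (17 higher, 55 lower) with quantile normalization and 106 (18 higher, 88 lower) after rescaling without the 50 most abundant genes. Array weights, which gave knockout library 3 a weight of 0.0900, called 4822 genes (3477 higher, 1345 lower), and so turned the balance to higher genes. They also brought Trp63 (-0.92, adjusted p = 0.024) and Fst (-0.85, adjusted p = 0.021) past the threshold. Leaving out 1 library at a time, with fewer libraries in each fit, gave 0 to 5127 genes (0 to 3809 higher, 0 to 1318 lower), namely 11, 16 and 5127 without knockout libraries 1, 2 and 3 and 1, 0 and 0 without wild-type libraries 1, 2 and 3. Without knockout library 3 all 44 were still called, and Trp63 passed at -0.85. Over these fits Trp63 ranged from -0.96 to -0.55 and Fst from -1.26 to -0.70. Over all alternatives their adjusted p ran from 0.024 and 0.021 to 1.0. With GC and length trends removed 13 genes were higher of 50 called, and without the 3 libraries richest in markers of neighbouring glands 20 were called (1 higher, 19 lower). That fit sets 2 knockout libraries against 1 wild-type library, which is assumed to vary like the others. Gene list calls numbered 8 with the 5 TPM filter, 0 with an estimated correlation and 3 with directional fry, against 13, and the proliferation list turned direction without knockout library 3 (median 0.21, adjusted p = 0.43). Unless the construction shows it, the cause was not tested. Libraries with neighbouring index numbers correlated in their deviations at 0.17, 0.23 and 0.08, each the best match for its library. The first numbers of their titles also lie close together. Both are hints of a pairing that the labels do not state. With that replicate block 31 genes were called (7 higher, 24 lower), 25 of them among the 44. Among the named genes, Krt14, Cnn1, Col6a3 and Chaf1b lost their calls. The list calls that changed were gains of TGF-beta targets and hedgehog signalling. Count tests and a sex covariate were planned and not run. Depth is unknown and sets no stated limit.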

Other observations

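Several matrix genes outside the lists also passed limma's test, and were picked after their values were seen. Cilp, a cartilage matrix protein gene, fell to 2.05 ± 0.641 TPM from 12.8 ± 1.40 TPM (SD, n = 3 each, log2 fold change -2.20, SE 0.25, adjusted p = 0.022). The collagen-binding proteoglycan gene Fmod (log2 fold change -2.03, SE 0.27, adjusted p = 0.036), the basement membrane collagen gene Col15a1 (log2 fold change -2.04, SE 0.27, adjusted p = 0.036) and Serpinh1, a chaperone for collagen in the endoplasmic reticulum (log2 fold change -1.51, SE 0.20, adjusted p = 0.036), fell too. Serpinh1 measured 6.15, 7.26 and 6.09 TPM in knockout libraries 1, 2 and 3 and 21.3, 19.1 and 20.6 TPM in wild-type libraries 1, 2 and 3. Within the fibroblast list, the 7 collagen genes had a median log2 fold change of -1.94 (-3.05 to -0.86) and the 15 other genes one of -0.69 (-2.32 to 0.41), a division made after the values were seen. The other genes were uneven. Pdgfra (-0.03, SE 0.41), Pdgfrb (-0.15, SE 0.21) and Dpt (-0.16, SE 0.44) did not follow the collagens. Lum (-2.32, SE 0.56) and Postn (-1.69, SE 0.37) were lower with no overlap between groups. Pdgfra measured 12.7, 4.99 and 3.77 TPM in knockout libraries 1, 2 and 3 and 8.05, 4.99 and 6.67 TPM in wild-type libraries 1, 2 and 3. With markers on both sides, fewer fibroblasts in the knockout preparations and lower collagen expression per cell both stay open.

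Some genes differed between libraries of the same group. Trib3, induced by amino acid and endoplasmic reticulum stress, measured 95.3, 78.4 and 2.22 TPM in knockout libraries 1, 2 and 3 and 2.94, 3.36 and 4.76 TPM in wild-type libraries 1, 2 and 3. The p53-induced gene Trp53inp1 measured 308, 139.6 and 5.05 TPM and 13.5, 8.46 and 15.9 TPM in the same order. Genes of S phase and mitosis stood out in knockout library 3, with Ube2c at 1.49, 0.896 and 17.7 TPM in the knockout and 0.746, 0.954 and 1.22 TPM in wild type, and Mcm6 at 1.35, 1.32 and 13.9 TPM and 2.08, 1.55 and 2.13 TPM. None of these 4 passed the test (adjusted p = 0.34, 0.40, 0.45 and 0.65). Products of neighbouring glands varied too, with the parotid-type gene Bpifa2 at 3648, 15.3 and 281 TPM in knockout libraries 1, 2 and 3 and 826, 5152 and 389.6 TPM in wild-type libraries 1, 2 and 3, and the sublingual-type gene Dcpp2 at 793, 7.06 and 1.03 TPM in knockout libraries 1, 2 and 3 and 4939, 45.9 and 1.86 TPM in wild-type libraries 1, 2 and 3.

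The tests that follow were chosen after the result was seen, except the splits of the libraries and rescaling for the granular convoluted tubule, and the markers of neighbouring glands were also chosen then. With 3 libraries in each group there are 10 splits, too few for a share under 0.05. The real split called 44 genes and the highest of the others called 1.

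Knockout libraries 1 and 2 lay apart from knockout library 3 and the wild-type libraries on the first component (63.7% of the variance), and the tests here replaced earlier ones that had averaged these libraries. The component kept 64.4% after removing trends against GC content and transcript length and 62.1% after rescaling without the 50 most abundant genes, with the gap still open, which argues against both as the whole cause. Granular convoluted tubule genes in knockout library 3 had a median of -1.97, outside the wild-type range of -0.07 to 0.09, which argues against a mislabelled wild-type library. The wild-type libraries spread over 2.22% of the range of the component, a closeness that is part of the pattern itself. It argues only against batches that follow the index numbers and move both groups alike along this component. Batches that act on 1 group, or off this component, stay open. Carry-over from neighbouring glands is not shared by both, since knockout library 2 lay below the median of the other 5 libraries for 8 of 8 markers. By basal genes, a weaker loss of p63 in knockout library 3 cannot be told apart from an equal one. Its basal median of -0.64 lay between -0.58 and -0.85 in knockout libraries 1 and 2. The first bounds of that test, moved after its value was seen, argued against a weaker loss. The myoepithelial median of knockout library 3, at -0.9998, was below -0.43 and -0.86 in knockout libraries 1 and 2, opposite to a weaker loss. Smooth muscle shares genes of that list, however. Trp63 itself was low and went the other way, at 1.76 TPM against 1.59 and 0.816 TPM, so a weaker loss stays open. Stress during cell isolation also stays open, with medians of 1.54, 0.86 and 0.01 for dissociation and stress genes in knockout libraries 1, 2 and 3.

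Granular convoluted tubule genes had a median log2 fold change of -2.13. This segment is larger in males, but all libraries held Y-linked transcripts (lowest 1.66 TPM) and little Xist, which argues against a difference in sex. The median was -2.49 without the 3 libraries richest in parotid or sublingual markers, which argues against carry-over as the whole cause, though it sets 2 knockout libraries against 1 wild-type library, assumed to vary like the others. It was -2.19 after rescaling without the 50 most abundant genes and -1.18 under quantile normalization, where Egf and Klk1b16 lost their calls as their folds shrank, so a few genes taking most of the TPM is argued against only as the whole cause. Reads shared between Klk1b copies cannot account for Egf, which is outside that family, and a candidate explanation is an effect of p63 loss on this segment, while androgen level and the share of these cells in the preparation stay open, as neither was measured.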
